A study of Mus musculus with 6 samples.

How the data were processed

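The series holds bulk RNA sequencing of RAW264.7 cells, a mouse macrophage-like line, given phosphate-buffered saline (PBS) or molybdenum disulfide (MoS2) at 6.25 µg/ml. There were 3 libraries in each of the 2 groups. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with a NEBNext Ultra kit, and paired-end reads came from an Illumina NovaSeq instrument. The length of the treatment is not given in the sources used here. Neither do the labels say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

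Per the submitters' processing notes, fastp 0.20.0, HISAT2 2.1.0 and featureCounts 1.6.1 were used. The deposited table holds whole-number read counts per gene, not normalized, for 55401 genes. The same notes name the build GRCh38, a human assembly, but all 55401 identifiers are mouse Ensembl genes, and 54349 of them occur in GENCODE M21 (GRCm38) with the same version and identical coordinates. Coordinates are therefore given on GRCm38 as in the deposited table. The treatment of reads that map to several places and the strand setting of the counting are not given in the sources used here. Counts of near-identical copies (ferritin genes, ribosomal protein genes, histones, Hspa1a and Hspa1b, classical MHC genes) and of genes that overlap another gene are uncertain for that reason. The columns of the table carry a letter and a number rather than the sample titles. They were matched by the letter, M for MoS2 and c for control, and by the replicate number. A gene symbol was found for 55141 identifiers, and 107 identifiers that share a symbol with a more abundant gene were kept under their identifier.

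The test of changed genes was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts of all 6 libraries. It used the treatment group as its only term, TMM scaling factors and the default low-count filter of edgeR. That filter asks for about 10 counts in 3 libraries and kept 12972 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are MoS2 over PBS with a prior count of 0.125. The standard error (SE) shown beside them was derived as the size of the fitted log2 change over the square root of F. It is approximate, and too small where a change is large and a group has few counts. Levels are CPM, the usual library-scaled read count, computed here with TMM factors, as mean ± SD over 3 libraries. Beside a group with 3 or fewer counts in all, the ratio is given with its exact 95% counting interval, which covers counting error only.

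There were 39 gene lists. Pathway, cell state, RNA quality and other cell type lists were fixed before the data were examined, as were the test, the filter, the alternative settings other than those said to be added later, and the rule for named genes. Of 846 list entries, 843 matched a gene of the table, 14 of them through an older symbol. The 29 lists with at least 5 tested members were tested with camera (limma, preset correlation of 0.01 between genes, Benjamini-Hochberg over the 29 lists), with camera's estimated correlation and with fry beside it. Camera compares the members of a list with all other tested genes. The number of members called is given over all genes tested. For 23 of the 29 lists the number adjusted over the list alone was the same, and the other 6 are given with their lists. Library composition was compared with exact two-sided permutation tests of 3 against 3 libraries, which cannot give a p under 0.1.

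Genes were named by 3 rules. The lead genes were the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, without unnamed gene models and pseudogenes. Up to 4 members of each list with the smallest adjusted p were named, whether or not they passed. Genes that the subject of the title brings to mind were named where tested (Nos2, Tnf, Il1b, Il6, Cd86, Arg1, Mrc1, Il10, Slc7a11, Gpx4, Acsl4, Hmox1, Fth1 and Tfrc). Together these gave 145 genes, of which 1 is not reported here.

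Alternative settings were RLE and upper-quartile factors, scaling by library totals alone, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a term for the replicate number, an adjusted p under 0.01, a test against a fold of 1.2, protein-coding genes alone, and leaving out each library in turn. Removal of each library's trend on gene length and GC content was added after the data were seen, as were random lists matched on expression and length (10000 per list) and counts of list members under other scalings. Genes of the random lists were drawn independently within classes of expression and length, so their percentiles ignore correlation between genes. Length and GC content were known for 99.9% of the tested genes.

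Total counts ran from 15767618 to 18412762 per library. No 2 libraries agreed within sampling noise, since the chi-square per degree of freedom within groups ran from 3.11 to 13.6, and each library was counted as its own replicate. The test was tried on counts simulated from the means and depths of these libraries with 200 of 12972 genes changed. It called 73.1% of genes changed 1.5-fold, 94.0% of genes changed 2-fold and 98.5% of genes changed 4-fold, and 6.35% of its calls were unchanged genes. With no gene changed it made 5 calls, and camera called 0 of 100 lists of unchanged genes. Genes were drawn independently in that simulation, whereas estimated correlations in the real lists called reached 0.613. It therefore does not test camera on lists of correlated genes. Only 200 genes were changed in the simulation, against 10466 called in the data. The shares of changed genes found and of false calls therefore do not carry over to these data. The 37 genes of the mitochondrial chromosome had 0 counts in each library, so the mitochondrially encoded list could not be tested.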

Results

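Gene expression was measured by RNA sequencing in 6 libraries of RAW264.7 mouse macrophage-like cells, 3 given PBS and 3 given 6.25 µg/ml of MoS2, a layered metal sulfide. Total counts per library were 17008020 to 17695883 with PBS and 15767618 to 18412762 with MoS2. Log-CPM values correlated across genes at a Pearson r of 0.988 to 0.993 within groups and 0.863 to 0.872 between groups, where genes are not independent replicates. The first principal component held 90.6% of the variance. The title of the series concerns MoS2, the tumour microenvironment and ferroptosis of tumour cells, and the comparison asks how the macrophage transcriptome differs between MoS2 and PBS.

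Csf3, Cxcl2, Ptgs2 and Ccl3, genes of inflammatory signalling, had far higher levels in MoS2-treated than in PBS-treated cells. Csf3, which encodes granulocyte colony-stimulating factor, went from 0.161 ± 0.0490 to 403 ± 10.1 CPM (SD, n = 3), and the neutrophil chemoattractant Cxcl2 from 11.1 ± 1.66 to 3482 ± 104 CPM. Ptgs2, the inducible cyclooxygenase, went from 9.42 ± 1.29 to 1476 ± 24.1 CPM, and the chemokine Ccl3 from 286 ± 6.55 to 14399.9 ± 297 CPM. Among the genes with the largest falls were the fractalkine receptor Cx3cr1, from 223 ± 7.13 to 6.77 ± 2.22 CPM, and Tlr13, an endosomal receptor for bacterial ribosomal RNA, from 104 ± 1.37 to 4.62 ± 0.643 CPM. Of 12972 genes tested, edgeR called 10466 at an adjusted p under 0.05, with 4964 higher and 5502 lower, and 5600 of them changed by an absolute log2 fold change of 1 or more (2524 higher and 3076 lower). Scaled by library totals alone, the split was 2334 higher and 8786 lower, because that scaling shifts genes by a median of -0.77 on the log2 scale against TMM.

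The rises were led by Csf3 (ENSMUSG00000038067.2, GRCm38 chromosome 11, 98701263 to 98703629), with a log2 fold change of 11.23 ± 0.13 (SE, edgeR adjusted p = 7.3e-16). The chemokine gene Ccl2 had 1 count in all PBS libraries and 1323 in the MoS2 libraries, a ratio of 2347 with a 95% counting interval of 420.4 to 92754. Uridine phosphorylase Upp1 rose by 9.09 ± 0.23 and the hydroxyisourate hydrolase Urah by 8.80 ± 0.19 on the log2 scale, the latter 9.83 without PBS replicate 1. Counts in all PBS libraries were 11 for Csf3, 4 for Upp1 and 19 for Urah, so the SE of these genes are too small. Cxcl2 (ENSMUSG00000058427.10, GRCm38 chromosome 5, 90903871 to 90905938) rose by 8.29 ± 0.11 and Ptgs2 (ENSMUSG00000032487.8, GRCm38 chromosome 1, 150100031 to 150108227) by 7.29 ± 0.10. The EGF receptor ligand Hbegf rose by 7.20 ± 0.11, Ccl5, which attracts T cells, by 6.75 ± 0.12, and the transcriptional inhibitor Id1 by 6.54 ± 0.13. Phlda1, the membrane glycoprotein gene Pdpn and Ccl3 (ENSMUSG00000000982.5, GRCm38 chromosome 11, 83647844 to 83649355) had log2 fold changes of 6.14 ± 0.14, 6.07 ± 0.23 and 5.65 ± 0.07. With the trend on gene length and GC content removed, Ccl5 and Ccl3 had 6.02 and 4.78. Adjusted p-values of these 12 genes by edgeR ran up to 2.8e-11, and each MoS2 library lay above each PBS library.

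The falls were led by the membrane protein gene Tmem51 (ENSMUSG00000040616.3, GRCm38 chromosome 4, 142030992 to 142084304), with a log2 fold change of -6.11 ± 0.23 (edgeR adjusted p = 2.8e-11), and by heparanase, Hpse, at -5.56 ± 0.19. Counts in all MoS2 libraries were 12 for Tmem51 and 29 for Hpse, so these SE are also too small. The transcription factor gene Zbtb45 had -5.36 ± 0.24, Cx3cr1 (ENSMUSG00000052336.7, GRCm38 chromosome 9, 119901616 to 120069879) -5.03 ± 0.14, and the host transcript of the miR-17 cluster, Mir17hg, -4.97 ± 0.35, or -6.35 without MoS2 replicate 1. Ranbp3l fell from 419 ± 7.34 to 15.3 ± 1.06 CPM, and the G protein-coupled receptor Gpr132 from 31.9 ± 2.06 to 1.17 ± 0.437 CPM. B3galt6, a glycosaminoglycan linker enzyme, the pro-apoptotic Bmf and Ppp1r26 had log2 fold changes of -4.63 ± 0.21, -4.59 ± 0.23 and -4.52 ± 0.28. Tlr13 (ENSMUSG00000033777.4, GRCm38 chromosome X, 106143204 to 106160493) had -4.50 ± 0.10 and the prostaglandin D synthase gene Ptgds -4.44 ± 0.25. Each MoS2 library lay below each PBS library for these 12 genes.

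**Figure D1:**
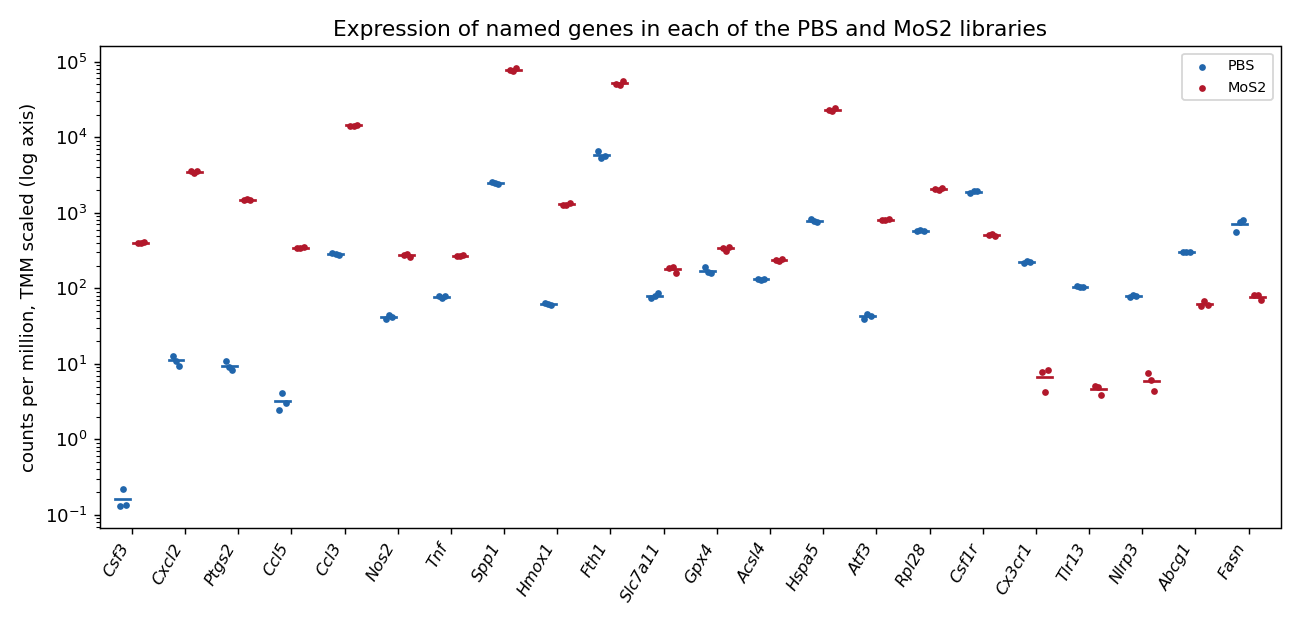
Expression of named genes in each library, as TMM-scaled CPM on a log axis, with PBS libraries in blue and MoS2 libraries in red. Points are the 3 libraries of a group and bars their mean, so that Csf3 lies at 0.161 CPM with PBS and 403 CPM with MoS2, while Acsl4, with the smallest change among those shown, has a log2 fold change of 0.86 (0.08 with library totals).

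Macrophage activation genes were compared because the title concerns the tumour microenvironment. In the classical activation list, 12 of 15 tested members rose and 2 fell, or 11 and 4 with library totals, with a median log2 fold change of 1.80 (camera adjusted p = 0.00160, and adjusted p = 0.216 with an estimated correlation). Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826.9, GRCm38 chromosome 11, 78920787 to 78960254), rose from 41.4 ± 2.51 to 272 ± 10.1 CPM, and the cytokine gene Tnf from 77.6 ± 1.97 to 269 ± 5.30 CPM. Ccl5 and the interferon-inducible chemokine Cxcl10 rose by 6.75 and 4.44 on the log2 scale. The pro-inflammatory cytokine Il1b stayed low in absolute terms, at 0.160 ± 0.238 to 9.0 ± 0.826 CPM with a log2 fold change of 5.75 ± 0.46 (edgeR adjusted p = 4.3e-08). Its PBS counts were 10, 0 and 1, and without PBS replicate 1 its log2 fold change was 8.25. Il6 had 1 count with PBS and 54 with MoS2, a ratio of 95.8 with a counting interval of 16.5 to 3852. The costimulatory receptor Cd86 rose from 2.31 ± 0.486 to 6.26 ± 0.738 CPM.

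In the alternative activation list, 3 members rose and 4 fell of 10 tested (2 higher and 4 lower adjusted over the list alone, 1 higher and 7 lower with library totals), and camera did not call it (adjusted p = 0.662, median -0.40). Clec10a, a galactose-binding lectin, and the transcription factor Klf4 had log2 fold changes of -3.64 and -1.61. The macrophage elastase Mmp12 rose by 3.26 ± 0.43 from 0.324 CPM, and Tgfb1 by 0.54 ± 0.06, which becomes -0.23 with library totals. The mannose receptor Mrc1 had 35 counts with PBS and 2 with MoS2, a ratio of 0.101 with a counting interval of 0.0118 to 0.395. Arg1 (15 and 2 counts) and Il10 (0 and 3 counts) were too low to be tested. The list of tumour-promoting macrophage factors had 10 members higher and 5 lower of 17 tested, or 8 and 8 with library totals, and was not called (camera adjusted p = 0.116). Its members with the smallest adjusted p were Ptgs2, Spp1, Hbegf and Ccl2. Spp1, which encodes the secreted glycoprotein osteopontin (ENSMUSG00000029304.14, GRCm38 chromosome 5, 104435118 to 104441050), rose from 2472 ± 46.8 to 77863 ± 3676 CPM, and took 0.323% of PBS counts and 5.95% of MoS2 counts.

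Ferroptosis is an iron-dependent cell death driven by lipid peroxidation, and its genes were examined in these macrophages, not in tumour cells. Of the 26 tested ferroptosis regulators 16 rose and 8 fell, a split of 12 and 12 with library totals, with a median of 0.79 (camera adjusted p = 0.0138, and adjusted p = 0.347 with an estimated correlation). That median stood at percentile 96.13 of random lists matched on expression and length, within their central 95%. Slc7a11, the cystine transporter subunit (ENSMUSG00000027737.10, GRCm38 chromosome 3, 49892526 to 50443614), rose by 1.15 ± 0.08, and Gpx4, which reduces lipid peroxides (ENSMUSG00000075706.10, GRCm38 chromosome 10, 80047166 to 80056439), by 0.98 ± 0.08. With library totals Slc7a11 and Gpx4 had 0.38 and 0.21. Acsl4, which activates polyunsaturated fatty acids, rose by 0.86 ± 0.06 with TMM and had 0.08 with library totals, where it was no longer called (edgeR adjusted p = 0.191, against at most 7.9e-07 in its other alternatives). Slc7a11 and Gpx4 are known to protect from ferroptosis and Acsl4 to promote it. The list members with the smallest adjusted p were Ptgs2, the spermidine acetyltransferase Sat1 (3.38 ± 0.08), the cyclohydrolase Gch1 (2.07 ± 0.08), which starts tetrahydrobiopterin synthesis, and the cytochrome P450 reductase Por (1.40 ± 0.06).

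Iron handling genes moved in both directions, with 14 members higher and 11 lower of 27 (15 higher and 11 lower adjusted over the list alone, 11 higher and 14 lower with library totals), and the list was not called (camera adjusted p = 0.0636). The iron storage genes Fth1 and Ftl1 rose from 5829 ± 629 to 51813 ± 2918 CPM and from 1248 ± 239.6 to 24134 ± 1762 CPM, and together with their copies elsewhere in the genome these counts are uncertain. Heme oxygenase, Hmox1 (ENSMUSG00000005413.8, GRCm38 chromosome 8, 75093621 to 75100589), rose from 61.8 ± 1.48 to 1292 ± 43.1 CPM, the siderophore-binding Lcn2 from 8.57 ± 1.75 to 408 ± 24.6 CPM, and the transferrin receptor Tfrc by 1.22 ± 0.06 on the log2 scale. Targets of the oxidative stress factor NRF2 had 17 members higher and 3 lower of 23, or 11 and 6 with library totals, with a median of 0.92 (camera adjusted p = 9.4e-05, and adjusted p = 0.216 with an estimated correlation), at percentile 90.78 of matched random lists. Besides Hmox1 and Fth1, they included the autophagy receptor Sqstm1 (2.79 ± 0.06) and esterase D, Esd (3.69 ± 0.07).

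Among metallothioneins and zinc or copper transporters, 8 rose and 2 fell of 13, but 2 and 7 with library totals, and camera did not call the list (adjusted p = 0.175). The copper chaperone Atox1 and the zinc importer Slc39a10 rose by 1.38 and 1.03, and the importer Slc39a1 fell to a log2 fold change of -0.99. Atox1 had 0.45 with the length and GC trend removed. Slc30a4 had 0.68, or -0.10 and no call with library totals. The molybdenum cofactor and molybdoenzyme list had 3 members higher and 4 lower of 8, or 1 and 6 with library totals, and was not called (camera adjusted p = 0.662). Within it, Mocs3, which transfers sulfur during cofactor synthesis, fell from 25.7 ± 3.99 to 1.94 ± 0.421 CPM, xanthine dehydrogenase Xdh and sulfite oxidase Suox had log2 fold changes of -1.33 and -2.19, and the molybdopterin synthase gene Mocs2 rose by 1.53.

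Targets of NF-kB, a transcription factor of inflammation, had 18 members higher and 7 lower of 26, or 13 and 12 with library totals, median 1.0 (camera adjusted p = 0.00484, and adjusted p = 0.216 with an estimated correlation), with Csf3, Cxcl2, Ptgs2 and Ccl3 at the smallest adjusted p. Interferon-stimulated genes had 21 higher and 5 lower of 30, or 15 and 10 with library totals, median 0.86 (camera adjusted p = 5.1e-04, and adjusted p = 0.216 with an estimated correlation). In that list the antiviral gene Rsad2 rose from 7.52 ± 0.953 to 324 ± 7.56 CPM, and Ifit2, the transcription factor Irf7 and Oasl1 rose by 3.31, 2.03 and 1.99 on the log2 scale. Immediate early genes had 19 higher and 6 lower of 26, or 16 and 7 with library totals, median 1.38 (camera adjusted p = 0.00137, and adjusted p = 0.216 with an estimated correlation), and included the MAP kinase phosphatases Dusp1 (3.86) and Dusp4 (3.06), the mRNA decay factor Zfp36 (3.41) and Ier5 (2.54).

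Receptors for chemokines and cytokines went the other way, with 3 members higher and 17 lower of 22 (4 higher and 17 lower adjusted over the list alone, 0 higher and 21 lower with library totals), median -1.55 (camera adjusted p = 4.1e-04, and adjusted p = 0.216 with an estimated correlation). The M-CSF receptor Csf1r, on which macrophage survival depends, fell from 1909 ± 64.6 to 513 ± 15.1 CPM, and the interleukin-6 receptor Il6ra from 77.6 ± 5.12 to 7.46 ± 1.08 CPM. The TGF-beta receptor Tgfbr2 had a log2 fold change of -2.48 ± 0.08. The inflammasome and pyroptosis list had 7 members higher and 6 lower of 15, or 4 and 9 with library totals, and was not called (camera adjusted p = 0.760). Its median was 0.09 and its mean -0.01, while camera's direction was up. The inflammasome sensor Nlrp3 fell from 79.8 ± 2.01 to 5.99 ± 1.6 CPM and the ATP-gated channel P2rx7 from 49.6 ± 3.49 to 8.67 ± 1.23 CPM. Nek7, which Nlrp3 needs for assembly, had -1.05, and Ninj1, which ruptures the membrane in lytic death, rose by 1.21.

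**Figure D2:**
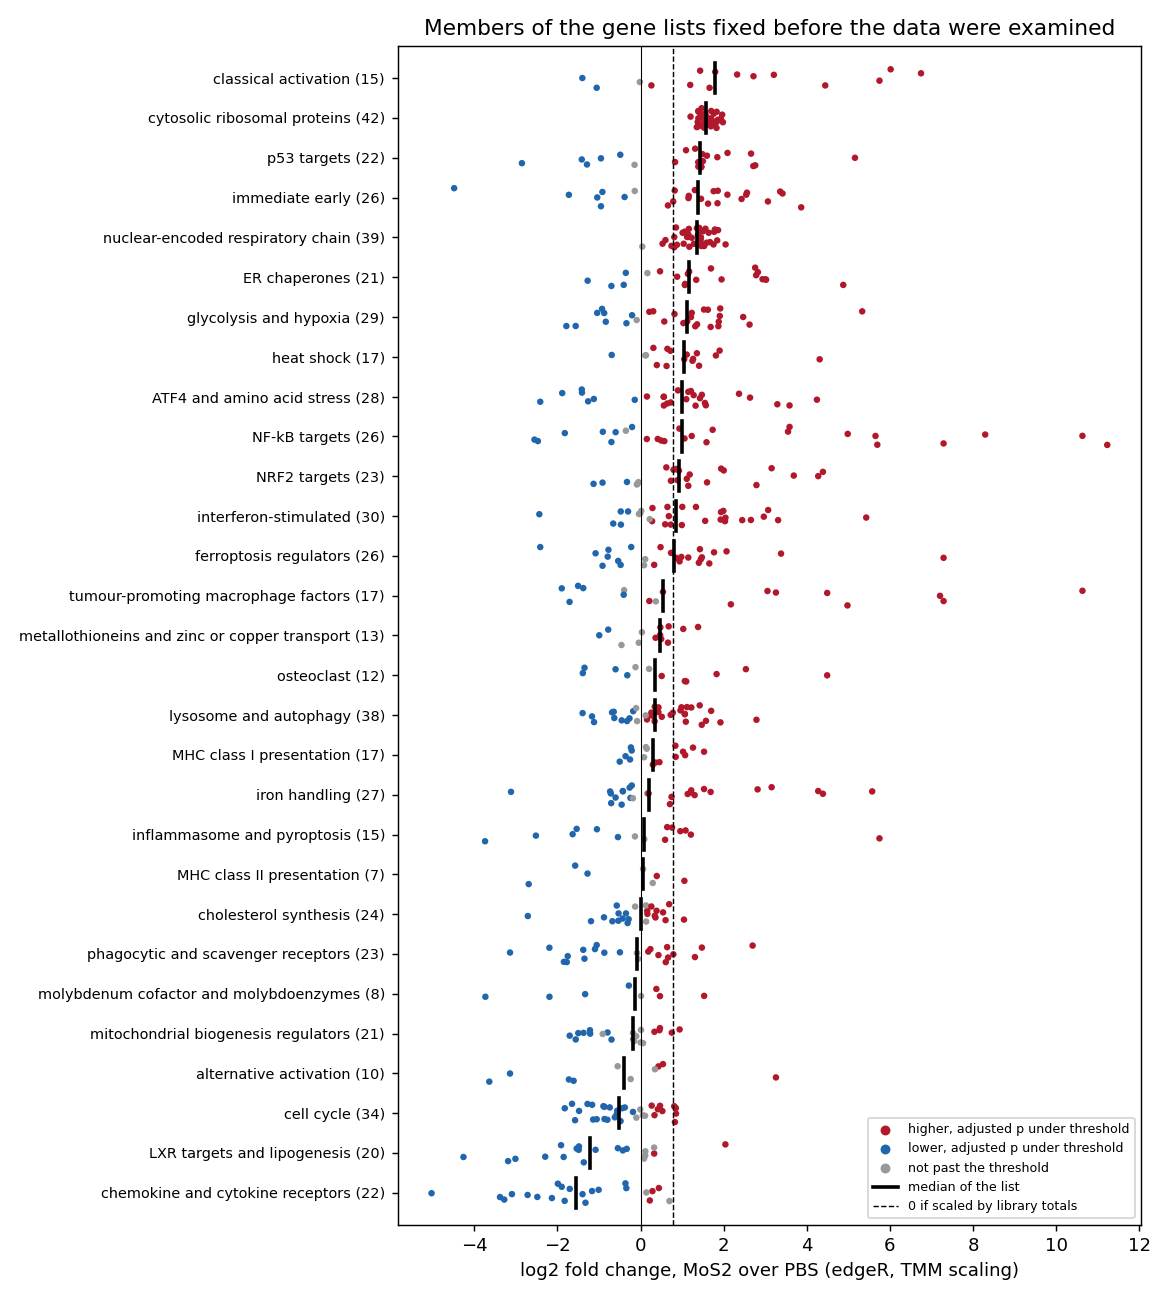
Log2 fold change of the tested members of 29 gene lists, MoS2 over PBS by edgeR with TMM scaling, with the number of tested members beside each name and a bar at each list's median. Red and blue points passed an adjusted p of 0.05, grey points did not, and the dashed line, drawn at the size of the median shift of -0.77, marks where 0 lies with library totals. Medians ran from -1.55 for chemokine and cytokine receptors to 1.80 for classical activation.

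Camera called 3 stress response lists higher at its preset correlation. ATF4 and amino acid stress genes had 21 higher and 7 lower of 28, or 14 and 12 with library totals, median 1.0 (camera adjusted p = 0.00160, and adjusted p = 0.312 with an estimated correlation), at percentile 91.36 of matched random lists. The stress transcription factors Atf3 and Ddit3 rose from 42.7 ± 3.16 to 809 ± 7.58 CPM and from 52.9 ± 5.49 to 634 ± 46.3 CPM. The phosphatase subunit Ppp1r15a and the transsulfuration enzyme Cth rose by 2.63 and 2.37. Chaperones of the endoplasmic reticulum had 16 higher and 4 lower of 21 (17 higher and 4 lower adjusted over the list alone, 14 higher and 6 lower with library totals), median 1.17 (camera adjusted p = 8.0e-05, and adjusted p = 0.228 with an estimated correlation). Their main chaperone Hspa5 rose from 785 ± 35.3 to 23067 ± 1074 CPM, and Calr, Pdia4 and Hsp90b1 rose by 3.02, 3.01 and 2.78. Heat shock genes had 14 higher and 1 lower of 17, or 9 and 6 with library totals, median 1.05 (camera adjusted p = 9.5e-05, and adjusted p = 0.216 with an estimated correlation), including Hspa1b (4.31, uncertain because of its near-identical neighbour Hspa1a), Hspe1 (1.90), Hspa8 (1.81) and Stip1 (1.25).

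Targets of p53 had 16 higher and 5 lower of 22, or 15 and 6 with library totals, median 1.42 (camera adjusted p = 0.00200, and adjusted p = 0.216 with an estimated correlation). The polo-like kinase gene Plk2 rose from 13.6 ± 0.692 to 487 ± 10.2 CPM, the cell cycle inhibitor Cdkn1a from 95.5 ± 2.86 to 647 ± 18.5 CPM, and Plk3 and the p53 ligase Mdm2 by 2.71 and 1.85. Cell cycle genes had 9 higher and 21 lower of 34, or 0 and 30 with library totals, median -0.51 (camera adjusted p = 0.0452, and adjusted p = 0.322 with an estimated correlation), and that call was also lost without MoS2 replicate 1 (camera adjusted p = 0.0529). The mitotic motor Kif11 and kinase Plk1 had log2 fold changes of -1.82 and -1.65, and the replication helicase subunits Mcm3 and Mcm7 of -1.17 and -1.28.

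Glycolysis and hypoxia genes had 20 higher and 8 lower of 29, or 16 and 12 with library totals, median 1.12 (camera adjusted p = 0.00171, and adjusted p = 0.216 with an estimated correlation), among them the glycolytic enzyme Pgk1 (2.62), the oxidoreductase Ero1l (2.47), the collagen hydroxylase subunit P4ha1 (1.92) and Ndrg1 (1.88). The nuclear-encoded respiratory chain had 38 higher and 0 lower of 39, or 30 and 2 with library totals, median 1.35 (camera adjusted p = 2.3e-12, and adjusted p = 0.273 with an estimated correlation). Cytochrome c, Cycs, rose by 2.04, and the ATP synthase subunits Atp5c1, Atp5b and Atp5f1 by 1.64, 1.59 and 1.56. Regulators of mitochondrial biogenesis had 5 higher and 9 lower of 21 (5 higher and 8 lower adjusted over the list alone, 0 higher and 18 lower with library totals) and were not called (camera adjusted p = 0.210), although the mitochondrial DNA factors Tfam, Twnk and Polg had -1.71, -1.56 and -1.50 (Polg -0.90 with the length and GC trend removed), and the coactivator Pprc1 -1.21. In the list of cytosolic ribosomal proteins 42 rose and 0 fell of 42, or 42 and 0 with library totals, between 1.2 and 1.98 on the log2 scale with a median of 1.58 (camera adjusted p = 1.8e-16, and adjusted p = 0.256 with an estimated correlation), with Rpl28, Rps23, Rpl27 and Rps20 at 1.83, 1.83, 1.70 and 1.96. Shorter genes rose more than longer ones across all genes: the median log2 fold change was 1.16 in the shortest of 10 equal length classes (median length 783 bases) and -0.35 in the longest (11935 bases), or 0.39 and -1.12 with library totals. Random lists matched to the ribosomal protein list on expression and length had a median of 1.2, and those matched to the respiratory chain list 0.94.

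Targets of the sterol-sensing receptor LXR and lipogenic genes had 2 higher and 14 lower of 20, or 1 and 19 with library totals, median -1.23 (camera adjusted p = 0.00625, and adjusted p = 0.216 with an estimated correlation). Fatty acid synthase, Fasn, fell from 708 ± 126 to 77.7 ± 6.86 CPM (log2 fold change -3.19, or -2.34 with the length and GC trend removed) and the cholesterol exporter Abcg1 from 302 ± 2.52 to 61.5 ± 5.11 CPM, the desaturase Scd2 had -1.48, and lipoprotein lipase, Lpl, rose by 2.04. Cholesterol synthesis genes had 10 higher and 11 lower of 24, or 1 and 20 with library totals, and were not called (camera adjusted p = 0.662). The sterol synthesis genes Hmgcs1 and Sc5d had log2 fold changes of -1.19 and -0.68, and Insig1, which holds back sterol synthesis, rose by 1.04.

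**Figure D3:**
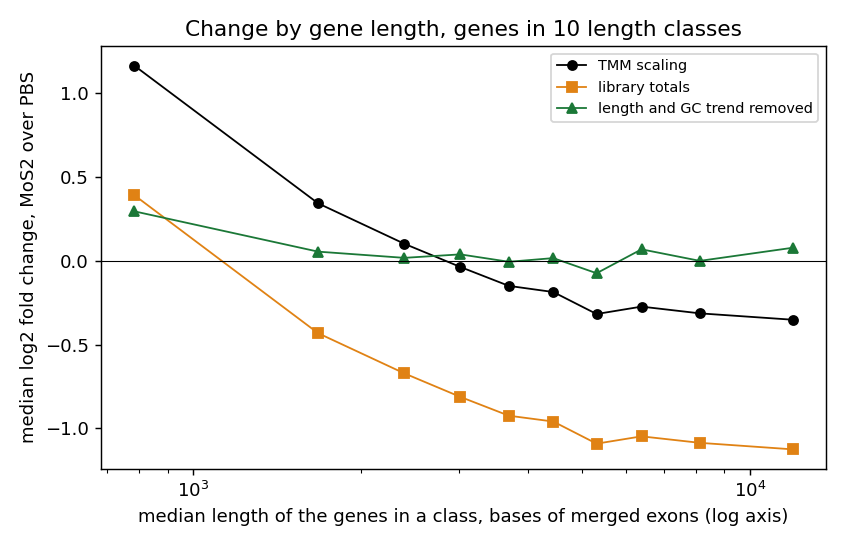
Median log2 fold change, MoS2 over PBS, of all tested genes in 10 classes of gene length, against the median length of each class in bases on a log axis. With TMM scaling (black) the median was 1.16 in the shortest class and -0.35 in the longest, with library totals (orange) it lay at 0.39 in the shortest class and -1.12 in the longest, and with the length and GC trend removed (green) it was 0.29 and 0.08.

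Lysosome and autophagy genes had 25 higher and 10 lower of 38 with TMM but 12 and 23 with library totals, median 0.34 (camera adjusted p = 0.0124, and adjusted p = 0.337 with an estimated correlation). That median stood at the 10.45 percentile of random lists matched on expression and length, on the lower side of their median of 0.57. Besides Sqstm1, the protease Ctsl, the autophagosome protein gene Gabarapl1 and the sialidase Neu1 rose by 1.92, 1.70 and 1.47. Phagocytic and scavenger receptors had 10 higher and 11 lower of 23, or 3 and 16 with library totals, and were not called (camera adjusted p = 0.662). The lipid receptor Trem2 and the endotoxin receptor Tlr4 had -1.38 and -1.75, and the complement receptor integrins Itgam and Itgb2 rose by 1.47 and 1.31.

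MHC class I presentation had 9 members higher and 5 lower of 17 (10 higher and 5 lower adjusted over the list alone, 4 higher and 11 lower with library totals) and was not called (camera adjusted p = 0.0692). The light chain B2m and the proteasome activators Psme1 and Psme2 rose by 1.26, 1.07 and 1.53 (B2m 0.56 with the length and GC trend removed), and H2-D1 by 0.84, which was 0.06 and no longer called with library totals. MHC class II presentation had 2 higher and 3 lower of 7, or 1 and 5 with library totals, and was not called (camera adjusted p = 0.867), with a median of 0.06, a mean of -0.54 and camera's direction down. The invariant chain Cd74 rose by 1.05, and the class II transcription factor Rfx5, H2-DMa and H2-Oa had -2.69, -1.57 and -1.28. RAW264.7 cells can form osteoclasts, and osteoclast genes had 6 higher and 4 lower of 12, or 5 and 7 with library totals, without a call (camera adjusted p = 0.454). In that list the gelatinase Mmp9 rose from 0.473 ± 0.369 to 10.7 ± 1.38 CPM (log2 fold change 4.49, or 5.30 without PBS replicate 3) and the proton pump subunit Tcirg1 by 1.10, and carbonic anhydrase Car2 and the osteoclast transcription factor Nfatc1 had -1.35 and -1.39.

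Most markers of other cell types were not detectable at a level that could be tested. Of 81 markers of fibroblasts, epithelium, T and NK cells, B cells, neutrophils, endothelium, erythroid and dendritic cells, 7 could be tested, none of them epithelial, neutrophil or erythroid. Counting tested and untested markers, 74 lay under 1 CPM of the library total in each library, the tested Itgae among them. Acta2 was the only untested marker above that level, at up to 1.52 CPM with MoS2 and 0.294 CPM with PBS. Each of those 8 lists had fewer than 5 tested members, so none had a list test. The B cell gene Ighm went from 120.0 ± 3.59 to 63.1 ± 4.75 CPM and the T cell gene Cd28 from 36.3 ± 1.76 to 4.51 ± 0.812 CPM, and these had the highest levels among the markers. The endothelial Vwf, the dendritic Zbtb46 and Itgae and the fibroblast Pdgfrb had log2 fold changes of -1.81, -2.12, -1.64 and -2.15. Vwf had -0.92 with the length and GC trend removed. Itgae had 34 counts with PBS and 6 with MoS2, lost its call in 9 alternatives, and had -1.09 without MoS2 replicate 1 (edgeR adjusted p = 0.148) and -2.53 without MoS2 replicate 3. The lymphocyte kinase gene Lck had 0.85 (0.08 with library totals, no longer called).

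Mean shares of counts differed between the groups, although no test could pass with this design. Genes detected overlapped, at 18161 to 19630 with PBS and 17660 to 18965 with MoS2. The ribosomal protein list took 4.43 ± 0.291% of counts with PBS and 7.82 ± 0.263% with MoS2 (SD, n = 3, exact two-sided permutation p = 0.1, 0.133 after Benjamini-Hochberg adjustment over 4 measures). The top 10 genes took 5.41 ± 0.202% and 19.2 ± 0.336% (exact p = 0.1, adjusted 0.133). Nuclear-retained RNA took 0.345 ± 0.0229% and 0.233 ± 0.0387% (exact p = 0.1, adjusted 0.133), and 19089 ± 807 and 18205 ± 679 genes were detected (exact p = 0.2, adjusted 0.2). The design cannot give an exact p under 0.1. Of the nuclear-retained RNAs, Neat1 fell from 824 ± 28.8 to 225 ± 18.1 CPM, Malat1 had a log2 fold change of 0.63 (-0.14 with library totals, no longer called), and Kcnq1ot1, at -0.25 ± 0.22, did not pass (edgeR adjusted p = 0.301). Ferritin heavy chain Fth1 took 0.761% of PBS counts and 3.96% of MoS2 counts, Hspa5 0.103% and 1.76%, and Ccl3 0.0374% and 1.10%. All 37 genes of the mitochondrial chromosome had 0 counts in each library. Whether they were left out before deposit or missing from the reference is not given in the sources used here, so this 0 bounds no share of the RNA.

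Camera called 17 of the 29 lists at its preset correlation, 14 higher and 3 lower. With an estimated correlation camera called 0 lists, with 4 at an unadjusted p under 0.05, and the adjusted p of the 17 lists ran from 0.216 to 0.347. Estimated correlations of the 17 lists ran from -0.0187 to 0.613. Those of classical activation (0.00096) and p53 targets (-0.0187) lay below the preset correlation, yet both lists lost their calls. Correlation between genes is therefore not the whole cause of the loss in these lists. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries and not from the number of genes, which raises p. The settings differ in both, and their shares in the loss were not told apart. Fry, which asks whether the members of a list move on balance one way without comparing them with other genes, called 19 lists higher and 8 lower. The medians of 13 of the 17 lists lay outside the central 95% of random lists matched on expression and length, and those of ferroptosis regulators, NRF2 targets, ATF4 and amino acid stress, and lysosome and autophagy lay inside it.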

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

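Removal of the length and GC trend was chosen only after the data were seen; the other alternatives here were planned. Of the 145 named genes, 137 kept their direction and their side of the threshold in each alternative that tested them, and 143 did apart from library totals. The filter of 1 CPM in 3 libraries left 141 of them and protein-coding genes alone 140, and the others were not tested there. The exceptions apart from library totals are Itgae, near 0.5 CPM, which lost its call in 9 settings (edgeR adjusted p up to 0.148, and 0.1697 with DESeq2), and Kcnq1ot1. Scaled by library totals alone, 2334 genes were called higher and 8786 lower, and Tgfb1, Slc30a4 and Malat1 turned to log2 fold changes of -0.23, -0.10 and -0.14, of which only Tgfb1 was still called (edgeR adjusted p = 0.00131, against 0.286 and 0.263). That scaling lowers log2 fold changes by a median of 0.77, which by construction turns genes with smaller rises, and 1231 genes called higher with TMM were called lower. Library totals also ended the calls of Acsl4, H2-D1 and Lck, and brought Kcnq1ot1 past the threshold at -1.02. With the length and GC trend removed, Kcnq1ot1 turned from -0.25 to 0.28, called in neither setting. Under the same removal the inflammasome and cholesterol synthesis lists changed direction at a camera adjusted p of 0.855 each, also uncalled in both settings (lowest over their alternatives 0.723 and 0.635). The cause was not tested. Leaving out 1 library moved 8 named genes by over 1.5-fold. They were Urah, Mir17hg, Mmp9, Il1b, Itgae, and, with 3 or fewer counts in a group, Ccl2, Il6 and Mrc1 (log2 fold changes from 10.63, 6.02 and -3.14 to 12.16, 7.55 and -6.27 without PBS replicate 2, PBS replicate 1 and MoS2 replicate 3). Removal of the length and GC trend moved 7 by as much, Ccl3, Ccl5, Atox1, Fasn, Polg, B2m and Vwf, and limma-voom moved Il1b, to 6.69.

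Counts of called genes in the other settings were 10468 with RLE factors, 10521 with upper-quartile factors, 11542 of 25215 genes with no low-count filter, 9943 with 1 CPM in 3 libraries, 10550 with DESeq2, 10453 with limma-voom, 9465 at an adjusted p under 0.01, 9152 against a fold of 1.2, 9128 of 11167 protein-coding genes, and 10391 with the length and GC trend removed. That removal turned the balance to 5409 higher and 4982 lower, with 22 genes called higher before now called lower and 145 the reverse. Without any 1 replicate, between 10177 and 10634 genes were called, 4843 to 5070 higher and 5334 to 5564 lower, and 5607 to 5886 had an absolute log2 fold change of 1 or more. The lists called were then 14 to 15 higher and 2 to 3 lower. MoS2 minus PBS ran from 3.23 to 3.52 percentage points for ribosomal protein counts, from -0.129 to -0.0911 for nuclear-retained RNA, from 13.6 to 13.9 for the top 10 genes, and from -1348 (without PBS replicate 1) to -612 for genes detected.

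With an estimated correlation camera called 0 lists higher and 0 lower, and fry called 19 higher and 8 lower, including all 17 lists called by camera. Lists were also run with RLE factors, 1 CPM in 3 libraries, the replicate block, the length and GC trend removed and each library left out. In those settings 24 of 29 lists kept direction and call, and 16 of the 17 called lists had adjusted p-values up to 0.0170. The cell cycle list ran from 0.0294 to 0.0542 and lost its call with RLE factors (0.0513), with 1 CPM in 3 libraries (0.0542) and without MoS2 replicate 1 (0.0529). Iron handling and MHC class I presentation were called in some settings, including with the length and GC trend removed (0.0156 and 0.0175), and reached 0.0711 and 0.0882 in others.

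No pairing of libraries by replicate number was seen, but 3 libraries per group cannot exclude it, and the labels do not say what the numbers share. Deviations from the group means of same-numbered PBS and MoS2 libraries correlated across genes at -0.0203, -0.0107 and -0.138, and no library correlated best with its own number. With the replicate number as a block, 10203 genes were called, and of the lists and named genes iron handling gained a call (camera adjusted p = 0.0491) and Itgae lost its own (edgeR adjusted p = 0.0678). At this depth the simulated test, with 200 genes changed, recovered 73.1% of genes changed 1.5-fold. Far more genes were called in the data, so that share does not carry over to them, although small changes can still be missed.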

Other observations

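The gene families grouped here by symbol, their comparison with matched random lists, the removal of the length and GC trend and the test of a stop of transcription were chosen only after results were seen. Toll-like receptor genes, which encode sensors of microbial molecules, fell in 8 of 8 tested members, with a median log2 fold change of -2.59, at percentile 0 of random lists matched on expression and length. Beside Tlr13, the endosomal nucleic acid sensors Tlr7 and Tlr9 fell from 183 ± 13 to 10.2 ± 2.34 CPM and from 14.3 ± 2.65 to 1.10 ± 0.641 CPM, and the lipoprotein sensor Tlr2 from 198 ± 1.56 to 33.7 ± 2.79 CPM. Chemokine genes rose in 11 of 12 members, or 10 higher and 2 lower with library totals, at percentile 100, and 2 of them had 3 or fewer PBS counts. Ccl4 rose from 82.3 ± 8.39 to 987 ± 70.8 CPM and Ccl9 from 336 ± 23.5 to 1182 ± 30.1 CPM, and 6 of the 12 genes are also in the fixed lists. Histone genes of the replication-dependent clusters rose in 17 of 18 members, 13 with library totals, at percentile 99.99, among them Hist1h2bc from 5.37 ± 0.837 to 159 ± 20.9 CPM and Hist1h1c from 104 ± 6.27 to 376 ± 22.9 CPM, while most members lay under 10 CPM and share sequence with their copies.

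Proteasome subunits rose in 36 of 38 members with a median of 1.07, or 25 higher and 6 lower with library totals. That median stood at percentile 97.17 of random lists matched on expression and length (their median 0.73), within their central 95%. The subunits Psmd8 and Psmd11 rose by 2.31 ± 0.07 and 2.28 ± 0.06, and the immunoproteasome subunit Psmb9 had -0.50 ± 0.12. Mitochondrial ribosomal proteins rose in 67 of 74 members with a median of 1.07, against 0.34 for matched random lists (percentile 100), and 40 were higher and 21 lower with library totals. Small nucleolar RNA host genes rose in 11 of 11 members, 9 with library totals, at percentile 99.71, such as Snhg1 by 2.34 ± 0.08 and Snhg12 by 2.62 ± 0.12. Families and the members given here were picked with their values in view. Solute carriers, a family of membrane transporters, fell in 116 of 202 members and rose in 48, or 160 and 26 with library totals, with a median of -0.45 at percentile 0.15.

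The real grouping of the libraries gave 10466 genes called by edgeR, and the highest count among the other splits into 3 and 3 was 0, with up to 40 genes at an unadjusted p under 0.05. Each other split placed PBS and MoS2 libraries together in each of its groups, so the treatment difference became spread within groups. Few gene calls are built into such splits. They cannot show how many genes would be called without a treatment difference, and no conclusion is drawn from the 0. Of the 10 splits, 1 gave as many genes, the real grouping itself. For the gene lists, 1 of 10 splits gave as many as the 17 lists called by camera with its preset correlation, again the real grouping, and the highest other split called 16. The 10 splits are too few for a share under 0.05.

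Ribosomal protein and respiratory chain lists stood higher than other genes by camera's preset correlation but not with an estimated one (adjusted p = 0.256 and 0.273), in data where short and abundant genes rose. A bias by gene length and GC content as the whole cause is argued against, since with each library's trend on both removed the medians stayed at 1.35 and 1.10 and camera with its preset correlation still called both lists. The removal was incomplete for short genes, as the shortest of 10 length classes kept a median of 0.29, so part of that bias may remain in these medians. For abundant and short transcripts of any function as the whole cause, the lists lay at percentiles 99.87 and 98.94 of matched random lists. Those lists were drawn gene by gene, whereas the estimated correlations here were 0.613 and 0.567. The highest expression class had a median of 240 CPM, while Rpl28 had 581 CPM with PBS, so abundance was matched only roughly. These percentiles therefore cannot decide on that cause. Matched random lists had medians of 1.2 and 0.94 against 1.58 and 1.35, so most of the rise may be shared with other short, abundant transcripts. A response to MoS2 stays open as a hypothesis, and differences in RNA fragmentation or extraction between the groups were not tested.

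Most genes were lower with MoS2 when scaled by library totals, with a median of -0.85 on the log2 scale. A few genes taking most of the counts were argued against as the whole cause. Without the 50 most abundant genes, which took 11.2% of PBS and 30.01% of MoS2 counts, the median was still -0.51. That test covers only those 50 genes. With TMM, medians were 0.27 and 0.60 in classes 9 and 10 of 10 classes of rising expression, so rises were spread over many abundant genes. A stop of transcription followed by decay as the whole cause is also argued against, as 110 genes of at least 5 CPM rose 1 log2 unit or more above the highest ribosomal protein list member at 1.98. That bar was set after results were seen, so the count describes these data and is no independent test. Zinc finger genes named Zfp, a class with short-lived mRNA, fell in 199 of 284 members (257 with library totals) with a median of -1.18. That is percentile 0 of matched random lists (median -0.55), as a larger loss of short-lived transcripts would give. No other class was tested for such a loss. Immediate early genes went the other way, with 19 higher and 6 lower of 26, a median of 1.38 and percentile 100. As a class that signals can induce, they cannot decide for or against such a loss. The Zfp genes alone do not settle it either. A lower output of most genes cannot be told apart from broad rises of abundant genes, since both lower the other genes against fixed totals. No measure of RNA per cell was used here, so the amount of RNA cannot be derived from these counts.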
